A study of Homo sapiens with 12 samples.

How the data were processed

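RNA sequencing measured gene expression in MCF10DCIS cells, a human breast line that models ductal carcinoma in situ, the stage of breast cancer still held within the ducts. The 12 libraries formed 4 groups of 3 replicates: wildtype cells with a scrambled mimic, wildtype cells with a miR-205 mimic, shRab27A cells with the scrambled mimic and shRab27A cells with the miR-205 mimic. A mimic is a synthetic double-stranded RNA that acts as a microRNA once inside the cell, and shRab27A marks cells that carry a short hairpin RNA against RAB27A. Groups and replicate numbers were taken from the sample titles. The comparator line is called wildtype and no control hairpin is named. Nothing in the labels says that replicates were separate cultures, so every p-value measures the spread between these libraries only.

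Per the labels' protocols, RNA was extracted with TRIzol, cleaned on columns and selected for poly(A) tails, and stranded libraries were prepared. Per the submitters' processing notes, DRAGEN 4.2.4, DESeq and the genome build GRCh38 were used, with no role or order stated. The DESeq version, the counting step, the annotation release and the strand setting of the counting are not given in the sources used here. The deposited table, made by the authors, holds counts for 60609 Ensembl genes in 12 libraries. Its name says normalised, but 0 of its values were other than whole numbers, no whole number from 1 to 30 was missing in any library, and median-ratio size factors ran from 0.707 to 1.253, so the values were handled as raw counts. Of the table's identifiers, 60340 received a symbol from the gene name table and 60590 with GENCODE 29 (GRCh38) added. The 45 entries for the Y copy of the pseudoautosomal region had a total count of 0.

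Total counts per library ran from 6435114 to 11814431. Before the data were examined, the groups, the comparisons, the tests, the gene lists, the rule for naming genes and a first set of alternatives were fixed. The fixed plan named limma-trend for normalised values and edgeR for raw counts. Because the table held counts, edgeR 4.0.16 was the main tool and limma-trend (limma 3.58.1) became an alternative. Genes were kept by filterByExpr, which left 14737, and scaled with TMM factors. A quasi-likelihood model with 1 mean per group (8 residual degrees of freedom) was fitted to all 12 libraries in R 4.3.3. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. The common dispersion was 0.0295, a biological coefficient of variation of 17.2%. Normalised counts are counts scaled to a library of 9.54e6 counts, given as mean ± SD over 3 replicates. Log2 fold changes are given with an approximate standard error (SE). It is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic, so it restates the test. Where all libraries of a group had a count of 0, a fold is a lower bound computed from 3 counts over the group. Where a group had 1 to 3 counts, a ratio is given with its exact interval or no fold is given. Intervals of shares are Wilson intervals, and intervals and floors cover counting error only.

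The comparisons were the mimic in wildtype cells, the mimic in shRab27A cells, the knockdown with scramble, the knockdown with the mimic, the interaction (the mimic effect in shRab27A cells minus that in wildtype cells), and both manipulations against neither. The 26 gene lists covered published miR-205 targets, Rab27 effectors and exosome release, microRNA processing and the silencing complex, RNA-loading proteins of extracellular vesicles, mesenchymal genes, epithelial junctions and identity, basal and myoepithelial genes, luminal genes, keratinocyte differentiation, invasion proteases, TGF-beta response, YAP/TEAD targets, negative regulators of PI3K/AKT, cell cycle, p53 targets, type I interferon response, NF-kB and cytokines, hypoxia and glycolysis, cholesterol synthesis, unfolded protein and integrated stress response, lysosome, fibroblast, immune and endothelial markers, mitochondrial-encoded transcripts and replication histones. The 23 lists with at least 5 tested members were tested with camera at its preset correlation of 0.01, adjusted over lists within a comparison. Camera was repeated with an estimated correlation, and fry was run beside it. Fry asks whether the genes of a list move, on balance, 1 way and compares them with no other genes.

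Genes were named by rule. In each of the first 4 comparisons RAB27A, RAB27B, ZEB1, ZEB2, ERBB3, VEGFA and MIR205HG were named, then the 10 largest rises and the 10 largest falls among called genes with a mean of at least 50 normalised counts in the higher group, no overlap between the groups and a proper symbol, then up to 4 called members with the largest change from each list. For the interaction up to 5 genes in each direction were named. Results for some genes that the rule names are not reported here. Library 1 of the wildtype scramble group stood apart. Leaving out each library was planned for genes, but giving the results without this library throughout, and leaving libraries out of the list and site tests, were choices made after seeing the data.

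Sites for miR-205-5p were searched in the longest annotated 3' UTR (at least 20 bases) of 19059 protein-coding genes of GENCODE 29, of which 12520 were among the tested genes, or 85.0% of them. A site was the 7mer ATGAAGG, which pairs with bases 2 to 8, and an 8mer site has an A after it. Genes with a site were tested against tested genes with a 3' UTR and no site by camera. Their p-values were adjusted over 5 comparisons, a step added after the unadjusted values were seen, and the planned unadjusted call of the mimic in wildtype cells was lost by it. The rank of the 7mer among 15972 7mers found in at least 100 genes is a description. Positions are 1-based on GRCh38.

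The alternatives were no filter, minimum counts of 10 or 50 in at least 3 libraries, library totals without TMM factors, a block on replicate numbers, only the groups compared, limma-trend with pseudocounts of 1, 0.5 and 5 or with quantile normalisation, voom with library quality weights, DESeq2 1.42.0, a minimum log2 change of 1, and leaving out each library in turn. Each line alone without each scramble library, simulated unchanged groups without wildtype scramble replicate 1, and the size of the mimic effect without each library, were added after seeing the data. The plan set no block on replicate numbers, because the labels do not say that a number marks a shared day. Each library's deviations from its group mean were also compared between same-number libraries of different groups. They correlated above 0.1 in 2 of 18 pairs (r from -0.368 to 0.203). In a test on simulated data with the same group sizes, 57 of 100 genes changed by a log2 of 1 and 86 of 100 changed by 2 were called, 12 of 155 calls (7.74%) were false, and a comparison with no change gave 0 calls. All simulated libraries had the same dispersion for a gene, so none stood apart. These rates may thus not carry over to the real libraries. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.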

Results

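RNA sequencing counts were available for MCF10DCIS cells in 4 groups of 3 libraries, with a miR-205 mimic or a scrambled mimic given to wildtype or to shRab27A cells. The experiment addressed which genes change with added miR-205, with knockdown of RAB27A, and with both. Total counts were 6632505, 10612156 and 10768414 for wildtype scramble replicates 1 to 3, 10112033, 11731372 and 11157844 for the wildtype mimic group, 10048829, 7994986 and 6435114 for the shRab27A scramble group, and 7781632, 11814431 and 9835533 for the shRab27A mimic group. Libraries of the same group correlated at 0.929 to 0.987 over genes on the log2 scale.

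Wildtype scramble replicate 1 stood apart from its group. Its mitochondrial transcripts made up 2.54% of counts (Wilson 95% interval 2.525% to 2.548%), against 8.52% (8.50% to 8.54%) in replicate 2 and 8.29% (8.27% to 8.30%) in replicate 3. The nuclear RNAs MALAT1 and NEAT1 took 1.21% of its counts (1.21% to 1.22%), against 0.260% (0.257% to 0.263%) and 0.318% (0.315% to 0.322%). It correlated at 0.966 with the shRab27A scramble libraries and at 0.934 with its own group, and on the first principal component (49.1% of the variance) it lay at -37.05, on the side of the shRab27A libraries, while its group mates lay at 39.29 and 41.47. The hypoxia and glycolysis genes moved with it: their median log2 level over the wildtype mimic mean was 0.91 in this library, -0.11 and -0.29 in its group mates, and 0.95 to 1.40 in the 6 shRab27A libraries. The mean mitochondrial share was 6.45% ± 3.39 (SD, n = 3) with scramble and 9.16% ± 0.04 with the mimic in wildtype cells, and 5.25% ± 0.15 and 5.83% ± 0.41 in shRab27A cells.

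**Figure D1:**
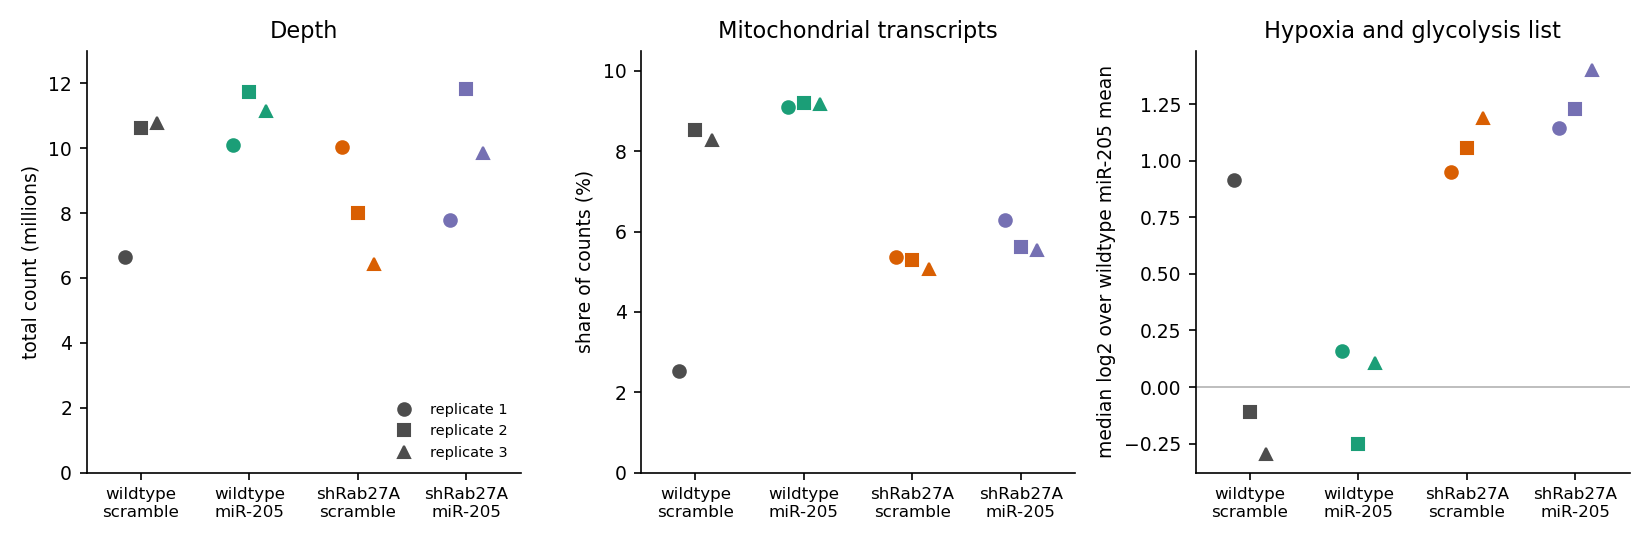
Total count (1e6 counts), share of counts from mitochondrial transcripts (%) and median log2 level of the hypoxia and glycolysis list over the wildtype mimic mean, for each of 12 libraries in 4 groups; each point is 1 library and its shape gives the replicate number. Wildtype scramble replicate 1 had a mitochondrial share of 2.54% and a hypoxia median of 0.91, and its group mates had 8.52% and 8.29% and medians of -0.11 and -0.29.

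RAB27A, which encodes the small GTPase that docks secretory vesicles at the plasma membrane (chromosome 15, 55202966 to 55319113), was lower in shRab27A cells with either mimic. Its normalised count was 101 ± 2.81 (SD, n = 3) in wildtype scramble, 73.9 ± 2.87 in wildtype mimic, 40.6 ± 9.80 in shRab27A scramble and 32.3 ± 2.44 in shRab27A mimic libraries. The raw counts were 75, 114 and 125, then 74, 84 and 85, then 57, 30 and 24, and then 25, 36 and 34, with no overlap of normalised counts between the lines. It fell by 1.30 on the log2 scale with scramble (SE 0.19, 2.46-fold lower, edgeR adjusted p = 0.00113) and by 1.20 with the mimic (SE 0.19, 2.29-fold lower, adjusted p = 5.44e-04). The mimic itself left RAB27A uncalled, at a log2 change of -0.45 in wildtype (adjusted p = 0.102) and -0.35 in shRab27A cells (adjusted p = 0.440). Its paralog RAB27B was not called in these 4 comparisons (adjusted p from 0.0724 to 0.977). The host transcript MIR205HG was not called with the mimic (adjusted p = 0.114 and 0.774), fell by 1.47 with knockdown and scramble (SE 0.43, adjusted p = 0.0421, lost in 11 of 12 leave-outs with a highest adjusted p of 0.167) and fell by 2.17 with knockdown and mimic (SE 0.43, adjusted p = 0.00219). With scramble its normalised counts were 271.6, 1455.4 and 1563.5 in wildtype replicates 1 to 3 and 428.1, 415.8 and 344.2 in shRab27A libraries, so wildtype replicate 1 lay below every shRab27A library. The MIR205 gene itself had a count of 0 in all 12 poly(A)-selected libraries, and ZEB1, a repressor of epithelial genes and a published miR-205 target, had 1 to 16 raw counts and was not tested.

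The mimic in wildtype cells raised the basal and myoepithelial list. COL17A1, the hemidesmosome collagen (chromosome 10, 104031286 to 104085957), rose from 250.1 ± 130.5 to 3015 ± 183 normalised counts (log2 3.57, SE 0.33, n = 3). Keratin 6A (KRT6A), found in stressed and basal epithelium, rose by 4.08 (SE 0.24). TOP2A, the topoisomerase of dividing cells, fell by 2.88 (SE 0.50), from 577 ± 503 to 77.7 ± 28.6, with the highest scramble value in replicate 1, and it was at -1.90 without that library. In the edgeR quasi-likelihood test 2039 of 14737 genes were called, 1065 higher and 974 lower, and without wildtype scramble replicate 1, a planned leave-out singled out after seeing the data, 3486 were called (1934 higher and 1552 lower), which kept 1912 of the calls (93.8%). Leaving out wildtype mimic replicate 1, 2 or 3 gave 987, 1037 and 1030. The share of higher calls was 52.2% with TMM factors and 22.9% with library totals, which lowers the log2 changes of this comparison by 0.155.

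Of 21 tested basal and myoepithelial genes, 16 rose with the mimic in wildtype cells, 0 fell and 5 were not called (18 rose when adjusted over the list alone). The median was 1.02 (camera adjusted p = 1.06e-15, and adjusted p = 3.60e-04 with an estimated correlation), and KRT6B rose by 1.66 (SE 0.09). Of 30 cell cycle genes 20 fell and 0 rose (22 lower adjusted over the list alone), with a median of -1.69 (adjusted p = 8.30e-12, but adjusted p = 0.346 with an estimated correlation), among them BUB1B (-2.56) and KIF20A (-3.01). Without scramble replicate 1, 16 of them fell, the median was -1.06 and KIF20A was at -2.09. The kinesins KIF4A (-3.16), KIF18B (-3.12) and KIF14 (-2.74) and the centromere gene CENPA (-2.66) were among the largest falls, and without scramble replicate 1, their highest scramble library, they were at -2.32, -2.31, -2.01 and -1.96. Of 20 p53 targets 8 rose and 0 fell (11 and 0 adjusted over the list alone; median 0.44, adjusted p = 8.90e-06, and adjusted p = 0.0557 with an estimated correlation). CDKN1A, the inhibitor of cyclin-dependent kinases, rose by 1.31 (SE 0.09) and the stress sensor SESN2 by 1.37 (SE 0.14). Of 23 unfolded protein and integrated stress genes 8 rose and 0 fell (11 and 0 adjusted over the list alone; median 0.42, adjusted p = 2.20e-05, and adjusted p = 0.253 with an estimated correlation), including the cystine transporter SLC7A11 (1.53) and CHAC1 (1.48).

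Extracellular proteases were among the largest rises. MMP9, a gelatinase gene (chromosome 20, 46008908 to 46016561), rose from 6.26 ± 4.36 to 297 ± 41.1 normalised counts (log2 5.57, SE 0.38, adjusted p = 5.09e-06, and 6.30 without scramble replicate 2), and the collagenase gene MMP1 rose by 5.39 (SE 0.55). SERPINB2, a plasminogen activator inhibitor, had a count of 0 in all 3 scramble libraries and was at least 57.0-fold higher with the mimic. Of 22 proteases and inhibitors, 8 rose and 3 fell, also when adjusted over the list alone. The mean was 1.05 but the median only 0.01, which turned to -0.15 with library totals (adjusted p = 0.0315, but 0.303 with an estimated correlation and 0.0658 without scramble replicate 1). Of 27 epithelial junction genes 10 rose and 3 fell (12 and 3 adjusted over the list alone; median 0.33, adjusted p = 0.00170, but adjusted p = 0.301 with an estimated correlation). With library totals 5 of them rose and 5 fell (median 0.17). The tight junction gene CLDN1 rose by 1.27 (SE 0.10) and CLDN3 fell by 0.90 (SE 0.25, lost in 5 of 12 leave-outs). Of 13 microRNA processing genes AGO3, AGO4 and TNRC6A rose and 0 fell (4 and 0 adjusted over the list alone; median 0.31, adjusted p = 0.00170, but 0.391 with an estimated correlation and 0.0856 without scramble replicate 1). Each of these 3 lost its call in 4 to 7 of the 12 leave-outs, at adjusted p values of up to 0.134. Library totals left 0 genes of the list called (median 0.16).

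Published miR-205 targets moved both ways with the mimic in wildtype cells. INPPL1, a lipid phosphatase gene of the PI3K pathway (chromosome 11, 72223701 to 72239105), fell by 0.73 (SE 0.12, adjusted p = 0.00274), from 999 ± 148 to 604 ± 42.1 normalised counts. The chromatin protein gene HMGB3 fell by 1.26 (SE 0.15), E2F5 by 1.11 (SE 0.17) and the angiogenic factor gene VEGFA by 0.90 (SE 0.18), from 12770 ± 3998 to 6831 ± 568. VEGFA is also on the hypoxia list, which was high in wildtype scramble replicate 1. With knockdown and scramble, which shares these controls, the VEGFA log2 change reached 0.324 without that library, the highest of the leave-outs. Part of the fall of VEGFA with the mimic may thus rest on that library. Of 25 tested targets 6 fell, 2 rose and 17 were not called (8 and 3 adjusted over the list alone), with a median of -0.23 that missed the threshold (adjusted p = 0.0569, and 0.0453 without scramble replicate 1). ERBB3, a receptor kinase gene, stayed at -0.01 (SE 0.14, adjusted p = 0.965), and ZEB2 was not called (-0.57, SE 0.42, adjusted p = 0.402). In this comparison 58 of the 83 called named genes kept their call whichever library was left out, and 0 changed sign. These genes were chosen as called, and the largest rises and falls also as not overlapping. A kept sign was thus close to fixed by the choice.

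Of the remaining lists only the mitochondrial one was called in this comparison. Counts of higher and lower members were 6 and 1 of 34 genes of Rab27 effectors and exosome release (9 and 1 adjusted over the list alone), 1 and 0 of 12 vesicle RNA-loading proteins (1 and 0), 3 and 3 of 18 mesenchymal genes (3 and 4), 4 and 1 of 14 luminal genes (5 and 2), and 4 and 2 of 12 keratinocyte genes (4 and 2, with a median of -0.23 but an upward test). They were 1 and 2 of 22 TGF-beta genes (1 and 4), 4 and 1 of 23 YAP/TEAD targets (4 and 3, with a median of 0.10 but a mean of -0.05), 3 and 1 of 17 PI3K/AKT regulators (3 and 1), 1 and 0 of 15 interferon genes (1 and 0), and 3 and 3 of 18 cytokine genes (3 and 3, with a median of 0.16 and a mean of -0.38). Hypoxia genes gave 0 and 2 of 24 (0 and 2), cholesterol genes 2 and 0 of 23 (2 and 0) and lysosomal genes 5 and 2 of 24 (5 and 2). Without scramble replicate 1, 11 of the cytokine genes rose and 2 fell (adjusted p = 1.88e-04). With library totals the medians of the Rab27, luminal, YAP/TEAD, PI3K/AKT and lysosomal lists turned negative. The balance of higher and lower members also turned for the Rab27 (3 and 4), YAP/TEAD (3 and 4), lysosomal (2 and 4) and cholesterol lists (1 and 2). It was 1 and 7 for the TGF-beta, 3 and 2 for the luminal and 2 and 1 for the PI3K/AKT list. The basal list had 14 higher and 0 lower under this scaling and the cell cycle list 0 and 21. The p53 list had 4 and 0, the stress list 5 and 0, the proteases 6 and 3 and the published targets 1 and 8. The call of the mitochondrial list (median 0.64, adjusted p = 0.00197, but 0.597 with an estimated correlation) owed most of its size to scramble replicate 1, where the list's median log2 level over the wildtype mimic mean was -2.58, against -0.16 and -0.23 in its group mates. Without that library the list was still called, at a median of 0.20 (adjusted p = 0.0452), with 6 of 13 genes higher. With all libraries it stood beside 0 of 13 genes called by edgeR, 0 at an unadjusted p under 0.05 and 0 by DESeq2.

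**Figure D2:**
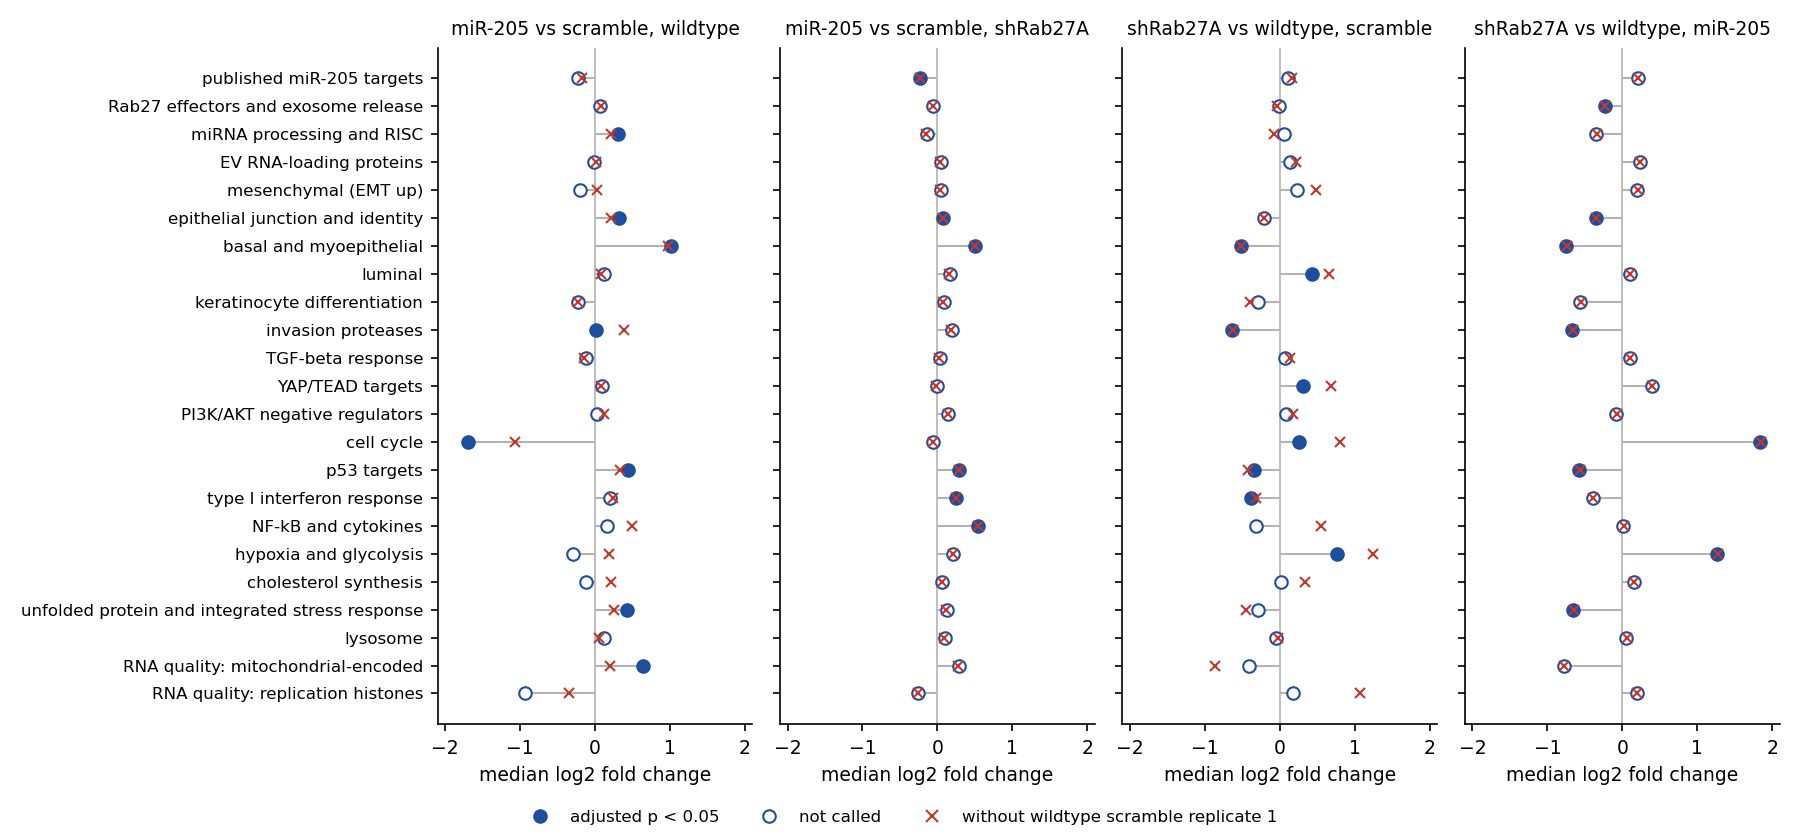
Median log2 fold change of the members of 23 gene lists in 4 comparisons; filled points have a camera adjusted p under 0.05, open points do not, and crosses give the median without wildtype scramble replicate 1. The basal and myoepithelial median was 1.02 and 0.50 with the mimic and -0.52 and -0.75 with the knockdown, and the hypoxia and glycolysis median with knockdown and scramble was 0.77 with all libraries and 1.24 without that library.

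The mimic in shRab27A cells asked which genes respond to miR-205 when RAB27A is lowered. HAS3, a hyaluronan synthase gene (chromosome 16, 69105564 to 69118719), rose from 167 ± 18.7 to 546 ± 47.8 normalised counts (log2 1.71, SE 0.12, n = 3, adjusted p = 3.02e-05), and AZGP1, which encodes a secreted glycoprotein, rose by 1.49 (SE 0.11). COL17A1 rose by 2.40 (SE 0.38) and PAPPA, a metalloproteinase gene, by 2.75 (SE 0.31). CHI3L1, which encodes a secreted chitinase-like protein, fell by 1.90 (SE 0.14) and the myeloid receptor gene TREM1 by 2.13 (SE 0.26). The edgeR quasi-likelihood test called 148 genes, 86 higher and 62 lower, with 2243 at an unadjusted p under 0.05. Without wildtype scramble replicate 1, which is in neither group, 1810 were called, all 148 among them. The log2 changes with and without it correlated at 1. That library acted through the shared spread, so keeping the calls was close to built in. Leaving out shRab27A scramble replicates 1, 2 and 3 gave 28, 28 and 64 calls, shRab27A mimic replicates 73, 30 and 29, and wildtype mimic replicates 86, 91 and 73. The share of higher calls was 58.1% with TMM factors and 23.8% with library totals, which lowers these log2 changes by 0.102.

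Of 21 basal and myoepithelial genes 5 rose and 0 fell in shRab27A cells (12 and 1 adjusted over the list alone), with a median of 0.50 (camera adjusted p = 8.20e-10, and 0.00201 with an estimated correlation). TP63, the transcription factor of basal cells, rose by 1.21 (SE 0.17), KRT15 by 0.79 (SE 0.16, lost in 9 of 12 leave-outs) and KRT6B by 0.73 (SE 0.09). Of 25 published miR-205 targets INPPL1 fell (-0.69, SE 0.12, 1194 ± 78.0 to 742 ± 71.9 normalised counts, adjusted p = 0.0228) and 0 rose (6 lower and 1 higher adjusted over the list alone). The list's median was -0.23 (adjusted p = 0.00795, and 0.0566 with an estimated correlation). Of 20 p53 targets DDB2 (0.86, SE 0.19) and CDKN1A (0.74, SE 0.09) rose and 0 fell (7 and 0 adjusted over the list alone; median 0.29, adjusted p = 2.48e-05, and 0.0566 with an estimated correlation). Of 18 cytokine genes RELB rose (0.62, SE 0.11) and 0 fell (1 and 0 adjusted over the list alone; median 0.54, adjusted p = 0.00795, but 0.540 with an estimated correlation). Among 15 interferon genes BST2 rose (0.73, SE 0.10, lost in 1 of 12 leave-outs) and 0 fell (2 and 0 adjusted over the list alone; adjusted p = 0.00810, but 0.456 with an estimated correlation). CLDN1 rose (0.61, SE 0.10) among 27 epithelial junction genes and 0 fell (4 and 0 adjusted over the list alone; median 0.08, which turned to -0.02 with library totals; adjusted p = 0.0139, but 0.456 with an estimated correlation).

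The largest falls in shRab27A cells also held RAB15 (-1.09, SE 0.20, lost in 5 of 12 leave-outs), a small GTPase gene of endosome recycling, the membrane protein gene CMTM4 (-1.14, SE 0.16) and the taurine transporter gene SLC6A6 (-1.05, SE 0.13). In the 30 cell cycle genes edgeR called 0 and DESeq2 0, with 2 higher and 0 lower at an unadjusted p under 0.05, and the median was -0.05 (adjusted p = 0.936). Other lists gave 2 higher and 0 lower of 23 YAP/TEAD targets (3 and 1 adjusted over the list alone), 2 and 0 of 24 lysosomal genes (2 and 1), 1 and 1 of 17 PI3K/AKT regulators (4 and 1), with DEPTOR, an inhibitor of mTOR, higher (1.22, SE 0.22, lost in 6 of 12 leave-outs), and 0 and 1 of 18 mesenchymal genes (2 and 4). Of the 36 called named genes 22 lost their call in at least 1 leave-out, and 0 changed sign, which the choice of called genes made likely. With library totals the published targets gave 0 higher and 3 lower, the p53 targets 1 and 0, the YAP/TEAD targets 1 and 1, the lysosomal genes 2 and 1 and the mesenchymal genes 0 and 2. INPPL1 was among the genes that lost their call (6 leave-outs, highest adjusted p = 0.144 without shRab27A scramble replicate 1), as were COL17A1 (0.0821), DDB2 (0.206), RELB (0.119) and CLDN1 (0.0985).

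Both mimic effects ran the same way for most called genes. COL17A1, PAPPA, KRT6B, CDKN1A and CLDN1 rose in both lines and INPPL1 fell in both. Across 14737 genes, which are not independent replicates, the log2 changes of both lines correlated at r = 0.308 (rho = 0.308), in comparisons that share no library. Both tests called 64 genes higher, against 6.2 if the calls were independent, and 40 lower, against 4.1, while 0 were called in opposite directions, against 10.2. The same dispersion estimate per gene served both tests, so the counts for independent calls are only a rough guide. Of the 148 genes called in shRab27A cells 136 had the same sign in wildtype cells, and of the 2039 called in wildtype cells 1633 had it in shRab27A cells.

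Genes with a site for miR-205-5p in the 3' UTR had lower mean log2 changes with the mimic than genes without; adjusted over 5 comparisons, the difference passed the threshold in shRab27A cells and not in wildtype cells. INPPL1 holds an 8mer site on chromosome 11 (72238798 to 72238804), at position 581 of a UTR of 888 bases, and VEGFA holds one on chromosome 6 (43784712 to 43784718). HMGB3 holds a pair of 8mer sites on chromosome X (150988906 to 150988912 and 150989661 to 150989667). ERBB3, which was not called with the mimic in either line, also holds an 8mer site (chromosome 12, 56102342 to 56102348). Of 14 tested published targets with an 8mer, 4 fell in wildtype cells and 10 were not called, and in shRab27A cells 1 fell and 13 were not called. Of 26 published targets with a UTR 19 held a 7mer, and E2F5, which fell in wildtype cells, held none. In wildtype cells 202 of 1746 genes with a site were lower (11.6%), against 6.37% of 10774 without, and their mean log2 change was 0.098 below the others (a difference of -0.098, camera adjusted p = 0.0666, and adjusted p = 0.0698 with an estimated correlation). The difference was -0.166 for the 677 genes with an 8mer (adjusted p = 0.00296) and -0.081 without wildtype scramble replicate 1 (adjusted p = 0.157). In shRab27A cells 21 genes with a site were lower (1.20%), against 0.343% of the others, with a difference of -0.093 (adjusted p = 0.00232, and adjusted p = 0.0143 with an estimated correlation), and -0.134 for 8mers (adjusted p = 1.86e-05). Against genes matched on UTR length and level the differences were -0.066 and -0.052 (adjusted p = 0.0998 for each). Among 15972 7mers, after adjustment for UTR length and level, this 7mer ranked 118 from the lowest in wildtype and 107 in shRab27A cells, and 194 and 113 without wildtype scramble replicate 1. With the knockdown the differences were 0.011 (adjusted p = 0.984) and 0.016 (adjusted p = 0.984), and for the interaction 0.005 (adjusted p = 0.984).

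**Figure D3:**
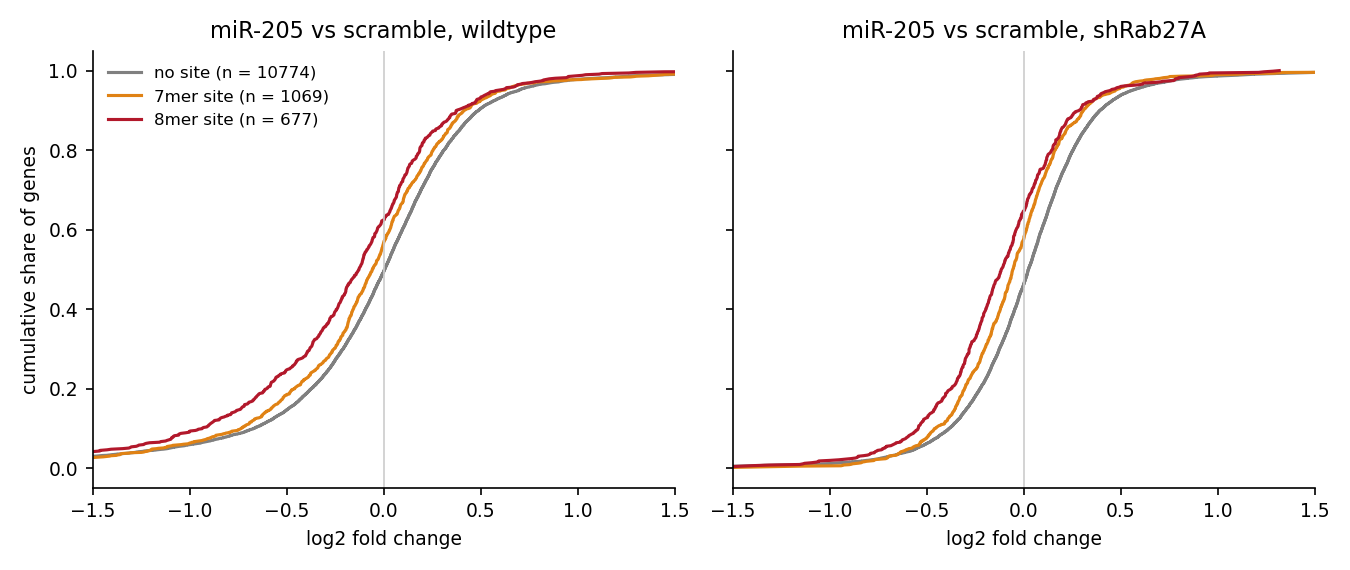
Cumulative share of genes against the log2 fold change with the mimic, in wildtype and in shRab27A cells, for 10774 genes with no site, 1069 with a 7mer site and 677 with an 8mer site for miR-205-5p in the 3' UTR; each line is 1 class of genes and the axis is drawn from -1.5 to 1.5. The 8mer curve lies to the left of the curve without a site in both lines, with mean differences of -0.166 and -0.134.

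The knockdown with scramble compared shRab27A and wildtype cells without added miR-205. TIMP3, an inhibitor of metalloproteinases (chromosome 22, 32801701 to 32863043), rose from 15.7 ± 5.36 to 259 ± 27.2 normalised counts (log2 3.99, SE 0.21, n = 3, adjusted p = 5.19e-07). SPDEF, a luminal transcription factor, rose by 2.55 (SE 0.13) and the receptor kinase gene AXL by 2.06 (SE 0.15). PLAU, which encodes urokinase, fell by 2.64 (SE 0.26), the membrane collagenase gene MMP14 by 2.54 (SE 0.23) and the cytokine gene IL1A by 2.79 (SE 0.21). TCEAL9 had a count of 0 in all 6 shRab27A libraries and 33 to 80 counts in the wildtype libraries, and was at least 59.6-fold lower. The edgeR quasi-likelihood test called 1677 genes, 703 higher and 974 lower. Without wildtype scramble replicate 1 it called 5594 (2824 higher and 2770 lower), which kept 1674 of the calls (99.8%), and leaving out wildtype scramble replicate 2 or 3 gave 846 and 795, shRab27A scramble replicates 1, 2 and 3 gave 964, 736 and 943. No control hairpin is named, so line and hairpin were not separated.

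Of 22 proteases and inhibitors 9 fell with the knockdown and scramble and TIMP3 alone rose (11 and 1 adjusted over the list alone), with a median of -0.64 (camera adjusted p = 3.24e-05, and 0.0900 with an estimated correlation). Of 21 basal and myoepithelial genes 11 fell and 3 rose (11 and 4 adjusted over the list alone; median -0.52, adjusted p = 0.00500, and 0.0900 with an estimated correlation). COL17A1 fell by 2.69 (SE 0.37) and LAMA3 by 1.75 (SE 0.28), and the oxytocin receptor gene OXTR rose by 1.30 (SE 0.34, lost in 5 of 12 leave-outs). Of 14 luminal genes 5 rose and 1 fell (7 and 1 adjusted over the list alone; median 0.43, adjusted p = 0.00290, but 0.272 with an estimated correlation). FOXA1, a pioneer factor of luminal cells, rose by 1.24 (SE 0.18) and ERBB3 fell by 0.47 (SE 0.14, adjusted p = 0.0474, lost in 11 of 12 leave-outs). Of 23 YAP/TEAD targets 5 rose and 2 fell (6 and 2 adjusted over the list alone; median 0.31, adjusted p = 5.86e-04, but 0.272 with an estimated correlation). AXL and TGFB2 (1.85, SE 0.27) rose and the ectonucleotidase gene NT5E fell by 1.40 (SE 0.17). Of 20 p53 targets 6 fell and 1 rose (6 and 1 adjusted over the list alone; median -0.34, adjusted p = 0.00500, but 0.263 with an estimated correlation), RRM2B falling by 0.82 (SE 0.12).

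Of 24 hypoxia and glycolysis genes 6 rose with the knockdown and scramble and 0 fell (13 and 0 adjusted over the list alone). The median was 0.77 (adjusted p = 2.09e-09, but 0.371 with an estimated correlation), and without wildtype scramble replicate 1 it was 1.24, with 23 higher. The carbonic anhydrase gene CA12 rose by 0.98 (SE 0.16) and the enolase gene ENO1 by 0.96 (SE 0.16), and in that library the list lay at the level of the shRab27A libraries. The mitochondrial list had a median of -0.41 in this comparison (adjusted p = 0.701), with 0 of 13 genes called by edgeR, 1 lower at an unadjusted p under 0.05 and 1 lower by DESeq2. Its median was -0.86 without wildtype scramble replicate 1 (adjusted p = 3.43e-10), with all 13 lower. Of 30 cell cycle genes CDT1, MCM5 and MCM7 rose (CDT1 and MCM5 lost in 10 and 8 of 12 leave-outs) and 0 fell (3 and 0 adjusted over the list alone; adjusted p = 0.0148, but 0.794 with an estimated correlation), and without that library 22 rose. Of 15 interferon genes 5 fell and 0 rose (5 and 0 adjusted over the list alone; median -0.39, adjusted p = 0.00636, but 0.272 with an estimated correlation and 0.0844 without that library), OAS1 falling by 1.34 (SE 0.27). The Rab27 effector and exosome release list gave 2 higher and 4 lower of 34 (2 and 4 adjusted over the list alone). The lower ones include RAB27A itself, which the hairpin targets, MLPH, which links Rab27 to myosin (-1.35, SE 0.31, lost in 4 of 12 leave-outs), and UNC13D (-0.67, SE 0.10). Of 12 vesicle RNA-loading genes 2 rose and 1 fell (4 and 1 adjusted over the list alone; median 0.14, adjusted p = 0.105). The 1 that fell was the vault protein gene MVP (-1.53, SE 0.19). Of the 86 called named genes 53 kept their call in every leave-out, and 0 changed sign, which the choice of called genes made likely.

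**Figure D4:**
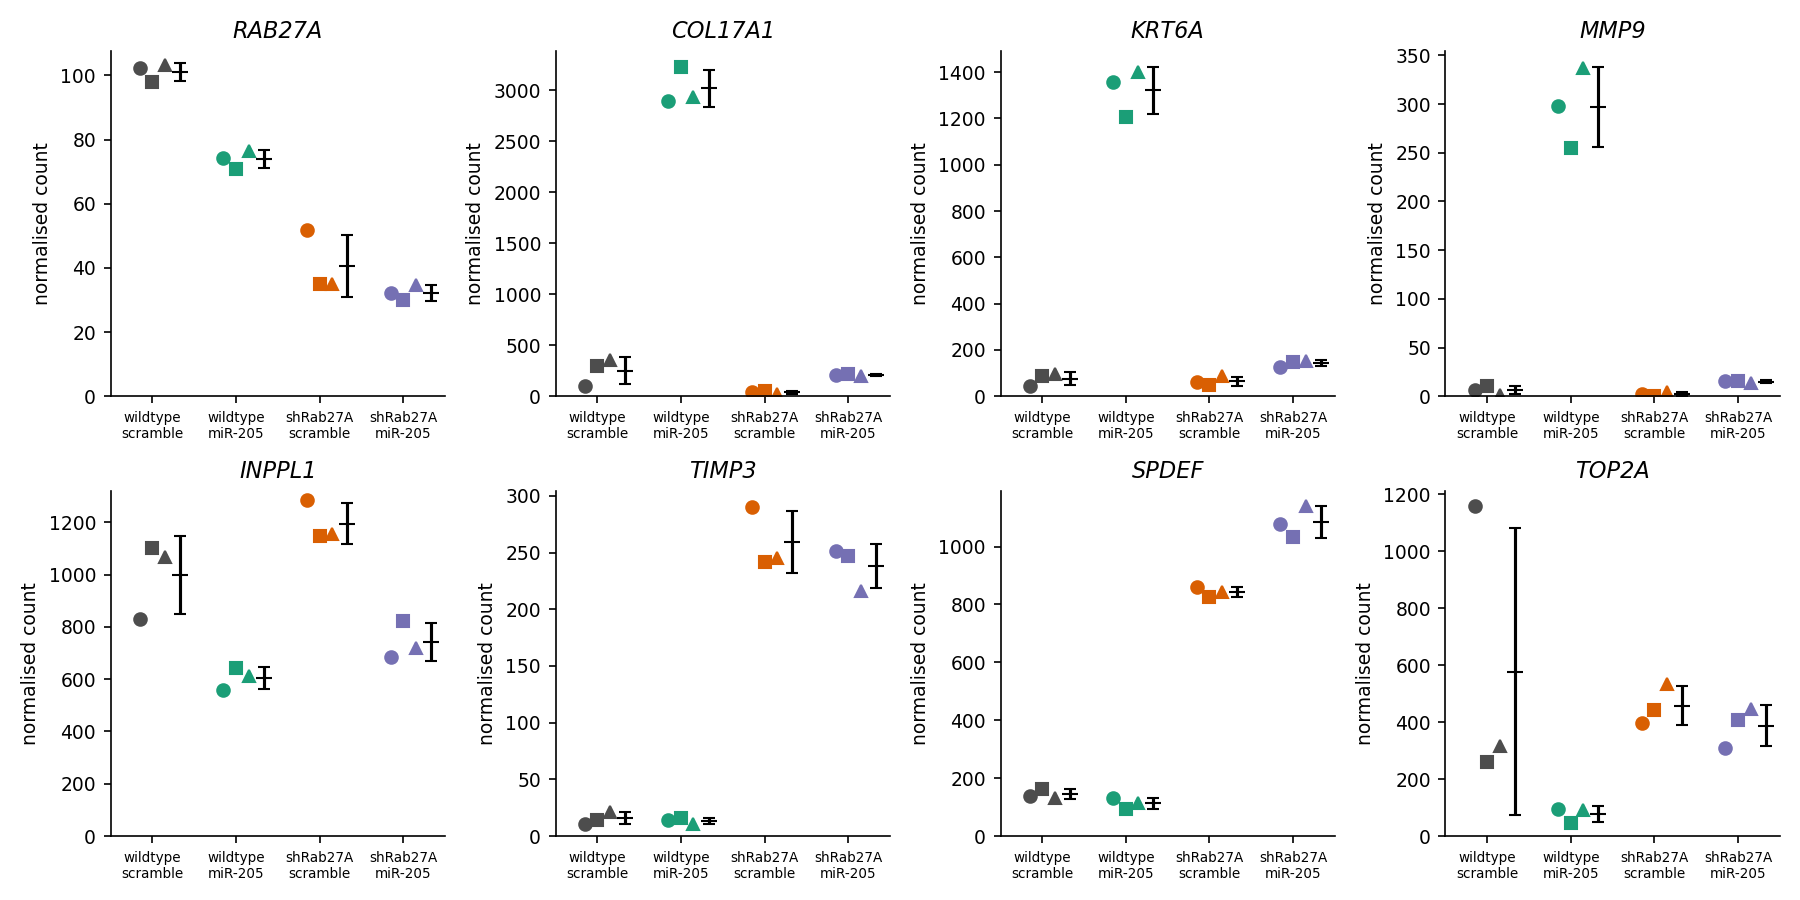
Normalised counts of 8 genes in 4 groups; each point is 1 library (circle, square and triangle for replicates 1, 2 and 3) and bars give the mean and SD of 3 replicates. COL17A1, KRT6A and MMP9 were highest in wildtype cells with the mimic (means of 3015, 1322 and 297), TIMP3 and SPDEF were higher in shRab27A cells with either mimic, and TOP2A in wildtype scramble was highest in replicate 1.

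The knockdown with the mimic compared both lines in the presence of miR-205. TIMP3 rose from 13.6 ± 2.63 to 238 ± 19.4 normalised counts (log2 4.11, SE 0.21, n = 3, adjusted p = 1.44e-07) and SPDEF from 113 ± 19.7 to 1084 ± 54.4 (log2 3.27, SE 0.14). MMP1 fell by 5.72 (SE 0.58, and -6.33 without shRab27A mimic replicate 1), MMP9 by 4.31 (SE 0.34), COL17A1 by 3.86 (SE 0.33), and the cell adhesion gene CEACAM6 fell by 4.42 (SE 0.32). The edgeR quasi-likelihood test called 5363 genes, 2599 higher and 2764 lower. Without wildtype scramble replicate 1, which is in neither group, it called 7662 with all 5363 among them, and without wildtype mimic replicate 2 it called 3516. Here too wildtype scramble replicate 1 acted through the shared spread, so keeping all calls without it was close to built in. Higher calls were 48.5% with TMM factors and 50.4% with library totals. The haem oxygenase gene HMOX1 fell by 4.22 (SE 0.74), with 178.5, 1980.8 and 358 normalised counts in wildtype mimic replicates 1 to 3, and without replicate 2 it fell by 2.57.

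Of 24 hypoxia and glycolysis genes 23 rose with knockdown and mimic and 0 fell (23 and 0 adjusted over the list alone), with a median of 1.27 (camera adjusted p = 3.28e-09, but 0.472 with an estimated correlation). EGLN3, an oxygen-sensing hydroxylase gene, rose by 2.64 (SE 0.34), ADM by 3.06 (SE 0.85, lost in 1 of 12 leave-outs) and VEGFA by 0.59 (SE 0.18, adjusted p = 0.0222, lost in 4 of 12 leave-outs). The mitochondrial list had a median of -0.78 (adjusted p = 0.0718, and 0.629 with an estimated correlation), with 0 of 13 genes called by edgeR, 3 lower at an unadjusted p under 0.05 and 2 lower by DESeq2. Its median stayed at -0.78 without wildtype scramble replicate 1 (adjusted p = 8.52e-07), with 12 lower. Of 30 cell cycle genes 26 rose and 0 fell (27 and 0 adjusted over the list alone; median 1.84, adjusted p = 7.42e-11, but 0.472 with an estimated correlation), BUB1 rising by 2.75 (SE 0.42) and MYBL2 by 2.69 (SE 0.58). Of 21 basal genes 12 fell and 1 rose (12 and 1 adjusted over the list alone; median -0.75, adjusted p = 3.12e-05, and 0.0228 with an estimated correlation), KRT6A falling by 3.21 (SE 0.23) and LAMA3 by 2.49 (SE 0.28). Of 22 proteases and inhibitors 13 fell and 3 rose (13 and 3 adjusted over the list alone; median -0.67, adjusted p = 2.04e-04, but 0.166 with an estimated correlation). Of 27 epithelial junction genes 14 fell and 4 rose (15 and 5 adjusted over the list alone; median -0.35, adjusted p = 0.0287, but 0.472 with an estimated correlation). OCLN fell by 1.02 (SE 0.12) and ELF3 rose by 1.59 (SE 0.17). Of 34 genes of the Rab27 effector and exosome release list 11 fell and 1 rose (11 and 1 adjusted over the list alone; median -0.24, adjusted p = 0.0312, but 0.166 with an estimated correlation). The genes that fell include RAB27A itself, which the hairpin targets. MLPH fell by 2.17 (SE 0.32) and the Rab27 effector gene EXPH5 rose by 1.19 (SE 0.21). Of 20 p53 targets 9 fell and 1 rose (11 and 1 adjusted over the list alone; median -0.58, adjusted p = 0.00276, but 0.166 with an estimated correlation), CDKN1A falling by 1.10 (SE 0.09). Of 23 unfolded protein and integrated stress genes 13 fell and 5 rose (13 and 5 adjusted over the list alone; median -0.65, adjusted p = 0.0341, but 0.478 with an estimated correlation), and SLC7A11 fell by 2.62 (SE 0.26).

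Of 25 published miR-205 targets 8 rose and 4 fell with knockdown and mimic, also when adjusted over the list alone (median 0.20, adjusted p = 0.380). ITGA5 fell by 1.41 (SE 0.10), ERBB3 by 0.81 (SE 0.14) and LRP1 by 1.32 (SE 0.28), while E2F5 rose by 1.48 (SE 0.17) and ZEB2 by 1.26 (SE 0.41, adjusted p = 0.0284, lost in 3 of 12 leave-outs). Of 13 microRNA processing genes 5 fell and 0 rose (5 and 0 adjusted over the list alone; adjusted p = 0.0718, and 0.0429 without wildtype scramble replicate 1), AGO4 falling by 0.71 (SE 0.12) and DICER1 by 0.56 (SE 0.13). Of 12 vesicle RNA-loading proteins 5 rose and 1 fell (5 and 1), MVP falling by 2.06 (SE 0.19) and the export factor gene ALYREF rising by 0.82 (SE 0.12). Of the 105 called named genes 88 kept their call in every leave-out, and 0 changed sign, which the choice of called genes made likely.

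The knockdown effects with scramble and with mimic, which share no library, correlated at r = 0.672 (rho = 0.683) across genes. They shared 569 higher genes, against 124 if independent, and 767 lower genes, against 183, with 8 in opposite directions, against 304. Here too the same dispersion estimate per gene served both tests, so the counts for independent calls are only a rough guide. TIMP3, SPDEF, AXL and TGFB2 rose in both and PLAU, MVP, MLPH and COL17A1 fell in both. The mimic effect in wildtype cells and the knockdown effect with scramble share their control libraries and correlated at r = -0.081. Simulated unchanged groups gave r = 0.499 from the shared controls alone, and the observed covariance lay 0.104 below the simulated one (a difference of -0.104). The simulation gave all libraries the same dispersion for a gene, so it held no library that stood apart. It also used differences of mean log2 levels where the observed values were edgeR fold changes, so the covariances compare only roughly. Without wildtype scramble replicate 1 the correlation was 0.133, against 0.567 in unchanged groups simulated for that set, and the covariance was 0.0687, against 0.0606, so the negative difference rested on that library.

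The interaction asked whether the mimic effect differs between the lines. KRT6A rose with the mimic from 75.8 ± 29.4 to 1322 ± 102 normalised counts in wildtype cells and stood at 65.1 ± 19.6 and 142 ± 13.8 in shRab27A cells, an interaction of -2.93 (SE 0.35, n = 3, adjusted p = 0.00984). NPC1, the lysosomal cholesterol transporter gene, had an interaction of -1.27 (SE 0.16, adjusted p = 0.00984), and KRT6B, a paralog of KRT6A with which reads can be shared, one of -0.94 (SE 0.13, adjusted p = 0.0159). AZGP1 had an interaction of 1.23 (SE 0.16, adjusted p = 0.00984) and the gelatinase gene MMP2 one of 0.90 (SE 0.16, adjusted p = 0.0451). The edgeR quasi-likelihood test called 38 genes, 11 higher and 27 lower, with 2097 at an unadjusted p under 0.05, and 700 (263 higher and 437 lower) without wildtype scramble replicate 1, all 38 among them. Without any other single library it called 0 to 29 genes: 29 and 8 without wildtype scramble replicates 2 and 3, 7, 0 and 0 without the wildtype mimic replicates, 0, 6 and 16 without the shRab27A scramble replicates and 16, 5 and 2 without the shRab27A mimic replicates. Where edgeR called 0, without wildtype mimic replicates 2 and 3 and shRab27A scramble replicate 1, the unadjusted p was under 0.05 for 1517, 1672 and 1474 genes, and DESeq2 on all libraries called 427. None of the 13 called named genes kept its call in every leave-out. The share of higher calls was 28.9%, and 50% with library totals.

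Of 21 basal and myoepithelial genes KRT6A and KRT6B had a lower interaction and 0 a higher one (5 and 0 adjusted over the list alone), with a median of -0.44 (camera adjusted p = 5.01e-07, and 0.00743 with an estimated correlation). Cell cycle genes had a median of 1.68 (adjusted p = 4.04e-14, but 0.431 with an estimated correlation), with 0 of 30 called by edgeR over all genes, 18 adjusted over the list alone, 21 at an unadjusted p under 0.05 and 13 by DESeq2. The cell cycle median was 1.08 without wildtype scramble replicate 1 (adjusted p = 3.34e-11), with 12 genes called. The basal median was then -0.66, the microRNA processing median -0.24 (adjusted p = 0.00651) and the stress median -0.23 (adjusted p = 0.0137). For microRNA processing genes the median with all libraries was -0.35 (adjusted p = 8.64e-05, but 0.431 with an estimated correlation), with 0 of 13 called by edgeR, 3 lower adjusted over the list alone, 3 at an unadjusted p under 0.05 and 2 by DESeq2. The stress list had a median of -0.45 (adjusted p = 0.00279, but 0.431 with an estimated correlation) and the Rab27 list one of -0.20 (adjusted p = 0.0228, but 0.258 with an estimated correlation and 0.0555 without wildtype scramble replicate 1). The hypoxia list had a median of 0.46 (adjusted p = 0.0129, but 0.934 with an estimated correlation), and without that library it was -0.05 (adjusted p = 0.931). Published miR-205 targets had a median of 0.04 (adjusted p = 0.918) with 0 called by edgeR, 6 at an unadjusted p under 0.05 and 2 by DESeq2.

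Both manipulations together against neither gave 3925 called genes, 1808 higher and 2117 lower, of which 408 and 769 changed at least 2-fold. TIMP3 rose by 3.87 (SE 0.21, adjusted p = 3.82e-07), SPDEF by 2.91 (SE 0.13, adjusted p = 1.58e-07) and AXL by 1.66 (SE 0.15, adjusted p = 3.08e-05), and none of these was called with the mimic alone. TREM1, which fell with the mimic in both lines and with the knockdown, fell by 5.06 (SE 0.24, adjusted p = 1.58e-07). These 4 genes were chosen after their values were seen. Without wildtype scramble replicate 1 the edgeR test called 7276 genes (3585 higher and 3691 lower), which kept 3874 of the calls (98.7%), without wildtype scramble replicate 3 it called 2422 and without shRab27A mimic replicate 3 it called 2314. The share of higher calls was 46.1% with TMM factors and 25.6% with library totals, which lowers these log2 changes by 0.143.

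**Figure D5:**
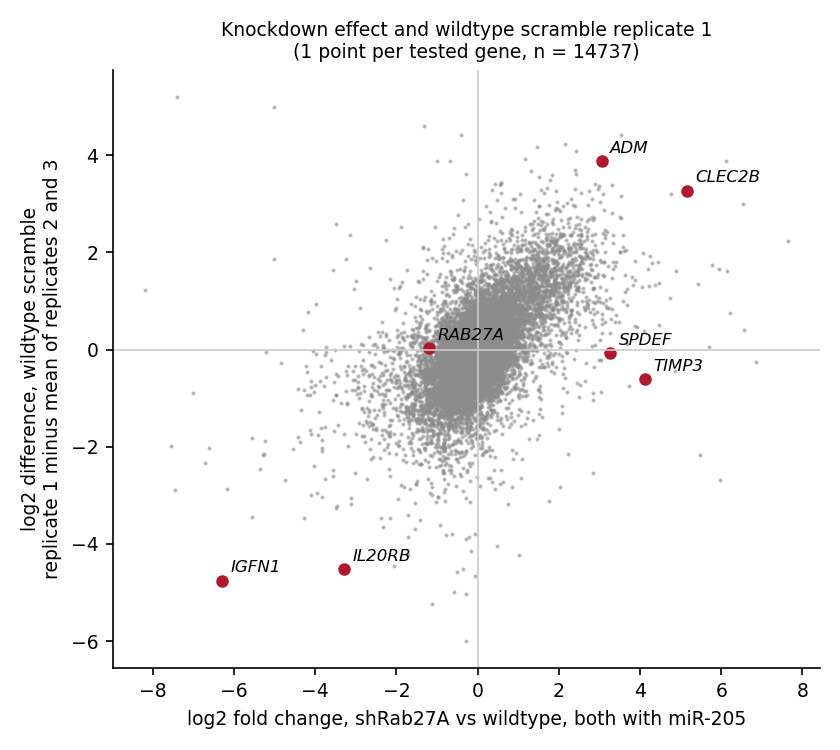
Difference of wildtype scramble replicate 1 from the mean of replicates 2 and 3 (log2, vertical axis) against the log2 fold change of shRab27A versus wildtype cells with the mimic (horizontal axis); each point is 1 of 14737 genes and 7 are named. The correlation across genes was 0.571, with ADM and CLEC2B high on both axes and RAB27A, TIMP3 and SPDEF near 0 or below on the vertical axis.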

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

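The tests of RAB27A in wildtype scramble replicate 1, of both counts of mimic calls, of the size of the mimic effect by line, of each line fitted alone without a library, of splits by wildtype group, and of hypoxia genes against depth and in replicate 1 were chosen after the result was seen.

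The interaction test flagged 10 genes because the estimated mimic effect differed between the lines at an adjusted p under 0.05 (log2 difference, edgeR adjusted p). KRT6A was at -2.93 (adjusted p = 0.00984), A2ML1 at -2.02 (0.0451), FLRT2 at -1.96 (0.0446), EPGN at -1.62 (0.0446) and IL1RN at -1.60 (0.0487). SERPINA1 was at 1.49 (0.0446), ARHGEF19 at 1.46 (0.0294), BCL11A at 1.28 (0.0446), AZGP1 at 1.23 (0.00984) and IGFBP2 at 1.15 (0.0487). Of 100 splits of the samples, 8 called as many genes as the real 38, the highest other 2057. The mark set beforehand against chance, under 5 of 100, was thus missed. The 7 others all kept the wildtype scramble and mimic groups as they are, so they hold the real mimic effect in wildtype cells. That grouping was chosen after the result was seen and does not undo the missed mark. Chance is left open for the interaction count. Of the 89 splits that mixed the wildtype groups 0 called as many, the highest 2. Mixing puts the mimic effect in wildtype cells into the spread within groups. Few calls could thus come with or without an interaction, and this count cannot decide. For the other 5 comparisons 1 of 10 splits, the real one, called as many genes, and these splits are too few for a share under 0.05. Real and highest other counts were 2039 and 0 for the mimic in wildtype cells, 148 and 0 in shRab27A cells, 1677 and 1562 for the knockdown with scramble, 5363 and 0 with the mimic, and 3925 and 83 for both against neither. The split with 1562 calls exchanged wildtype scramble replicate 1 for shRab27A scramble replicate 1, and the remaining splits of that comparison called 0.

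Wildtype scramble replicate 1 stood apart from replicates 2 and 3. Thinning replicates 2 and 3 to its depth gave an SD of log2 differences of 0.443, against 0.894 and 0.916 for pairs with replicate 1, so depth alone did not give the spread. Of 39 genes low in shRab27A cells its median share was 0.482, which met the prediction for a wrong label or admixed RNA, but RAB27A lay -0.029 of the way to the shRab27A mean and TIMP3, SPDEF and TCEAL9 -0.030, -0.013 and -1.33, which argues against it. Nuclear-retained RNAs other than MALAT1 and NEAT1 moved by 0.011 (9 genes, 5 above 0), against more nuclear RNA. Heat shock and immediate early genes were higher by a median log2 of 2.08 (12 genes, 11 above 0, from -0.46 to 3.54), which may reflect a stress response of that culture.

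With all 12 libraries fitted together the mimic called 13.8 times as many genes in wildtype as in shRab27A cells, and 1.93 times as many without wildtype scramble replicate 1. With each line fitted alone the order turned, with 512 genes called in wildtype and 1006 in shRab27A cells. Fitted alone without that library, wildtype cells gave 4322, without replicate 2 or 3 they gave 126 and 85, and shRab27A cells without scramble replicate 1, 2 or 3 gave 311, 305 and 1266. Which line called more genes thus depended on the fit and on that library, and whether the lines differ in their number of responding genes is left open. By size, without wildtype scramble replicate 1 the mean shift of genes with a site was 1.16 times as large in shRab27A cells (-0.094 against -0.081; 95% bootstrap interval 0.883 to 1.62 over genes, which are not independent replicates, 1000 draws). With all libraries the order turned, at -0.093 against -0.098, at -0.134 against -0.166 for 8mers, and at -0.052 against -0.066 beside matched genes. The estimated SD of true changes without replicate 1 was 0.264 against 0.397, a ratio of 0.664. It was taken over the more highly expressed genes only, with the mean squared SE subtracted from the variance. Over 23 sets with 1 or 2 libraries left out, the share of the shift ran from 0.825 to 1.242 and the ratio of SDs from 0.436 to 0.731. The share was the larger in all 23, but it covers all tested genes with a 3' UTR, and the sets have most libraries in common. Less mimic in shRab27A cells is left open, because the shift in wildtype cells missed its threshold without replicate 1 (adjusted p = 0.157), and no biological explanation was tested.

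Hypoxia genes were higher in shRab27A libraries, and mitochondrial transcripts made up 5.08% to 6.30% of their counts, against 8.29% to 9.19% in wildtype libraries other than scramble replicate 1. Depth did not give this, since the deepest shRab27A library had a median of 1.23 and a mitochondrial share of 5.63%. Wildtype scramble replicate 1 had a median 1.14 above its group mates, and across genes, which are not independent replicates, its difference from them correlated at 0.571 with the knockdown effect in mimic-treated cells. These values could reflect a culture state that wildtype cells can also take on (0.571), and the design does not separate this from an effect of the hairpin.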

How the results depend on the processing

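Counts of calls depended on the libraries and the tool. The share of higher calls depended on the scaling, at 52.2% with TMM factors and 22.9% with library totals for the mimic in wildtype cells. Alternatives chosen after seeing the data were limma-trend on TMM-scaled counts, library totals, voom quality weights, and the lists, site tests and overlaps under further settings. A count of 10 in 3 libraries was the plan's filter for normalised values. An estimated correlation and fry were its alternatives for the lists. Of 8208 values of named genes under alternatives 7299 kept direction and side of the threshold, 866 fell short of it, 19 passed it and 24 turned. Most named genes were chosen because they were called, which made a turn unlikely. Counts are higher and lower, in the order mimic in wildtype, mimic in shRab27A, knockdown with scramble, knockdown with mimic, interaction and both against neither. Leaving out 1 library gave 537 to 1934 and 423 to 1552, 16 to 953 and 10 to 857, 361 to 2824 and 375 to 2770, 1588 to 3812 and 1875 to 3850, 0 to 263 and 0 to 437, 1076 to 3585 and 1217 to 3691; the overlap of mimic calls ran from 22 to 918 (main 104) and the site difference from -0.113 to -0.081, -0.097 to -0.091, -0.004 to 0.028, 0.011 to 0.022 and -0.013 to 0.020. A minimum log2 of 1 gave 224 and 401, 29 and 13, 143 and 388, 1015 and 937, 6 and 19, and 408 and 769, overlap 27. Library totals gave 553 and 1863 for the mimic in wildtype and 1119 and 3251 for both against neither, overlap 197. Only the groups compared gave 309 and 203, 540 and 466, 128 and 138, and for both against neither 675 and 772, overlap 159. Quality weights gave 2581 and 2285, 1505 and 1252, 3176 and 3417, 4207 and 4310, 664 and 944, 4100 and 4392, overlap 1346. For the mimic in shRab27A cells and the interaction, no filter gave 308 and 244, 410 and 269 (overlap 269), a replicate block 43 and 30, 1 and 3 (overlap 54), and DESeq2 316 and 276, 171 and 256 (overlap 328); a count of 50 gave 95 and 120, and 20 and 44. With 7mer-A1 sites the wildtype difference was -0.086 (adjusted p = 0.141), and against matched genes it was -0.014 and -0.001 for the knockdown. Lists called numbered 8, 6, 8, 8 and 6, with an estimated correlation 1, 1, 0, 1 and 1, with fry 12, 3, 12, 15 and 2, with a block 9, 7, 8, 8 and 6, and without wildtype scramble replicate 1 8, 10, 9, 11 and 4. List medians of the mimic and knockdown comparisons did not move with genes at 0 set to their bound, which was not computed for the interaction. Uncalled genes turned: RAB27B with the mimic in wildtype (-0.009) to 0.016 with no filter and from -0.162 to 0.161 without single libraries, 0.001 and 0.002 among them; ERBB3 (-0.013) to 0.007 with no filter, 0.014 with limma and from -0.169 to 0.093 without single libraries, 0.028 and 0.073 among them; ZEB2 with the mimic in shRab27A (0.017) to -0.084 with library totals, -0.048 with the block, -0.157 with weights and from -0.281 to 0.158 without single libraries, -0.192 among them; VEGFA with knockdown and scramble (0.024) to -0.016 with totals, -0.029 with quantiles and from -0.083 to 0.324 without single libraries, -0.014 and -0.072 among them; RAB27A interaction (0.10) from -0.017 to 0.324 without single libraries, -0.010 among them; ZEB2 interaction (0.582) to -0.067 with weights. Without wildtype scramble replicate 1 the hypoxia list in the interaction turned (adjusted p = 0.931). The cause was not tested. Depth limits genes near 10 counts, such as ZEB1.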

Other observations

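The TCEAL9 test was chosen after the result was seen.

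Markers of other cell types and of RNA quality were read beside the comparisons. Of 4 tested fibroblast markers 1 rose and 1 fell with knockdown and mimic (median 0.89), and 0 rose and 1 fell with scramble (median 0.14, and 1 higher and 1 lower at an unadjusted p under 0.05; DESeq2 called 0 higher and 1 lower). The fibroblast protease gene FAP fell with the knockdown by 2.21 (SE 0.27, edgeR adjusted p = 3.73e-04) with scramble and by 2.26 (SE 0.26, adjusted p = 5.18e-05) with the mimic, while PDGFRA, a receptor gene of fibroblasts, rose by 1.91 with the mimic (SE 0.57, adjusted p = 0.0195, lost in 3 of 12 leave-outs). Of the immune markers CD68 and CSF1R were tested, with medians of -0.97 with the mimic in wildtype cells, -0.57 in shRab27A cells, -1.52 with knockdown and scramble and -1.12 with knockdown and mimic. The lysosomal gene CD68 fell with the knockdown by 1.73 (SE 0.31, adjusted p = 0.00409) with scramble and by 2.32 (SE 0.32, adjusted p = 2.27e-04) with the mimic. The receptor gene CSF1R fell by 1.93 (SE 0.39, adjusted p = 0.00725) with the mimic in wildtype cells, from 35.7 ± 13.8 to 9.31 ± 3.30 normalised counts, and by 1.31 (SE 0.39, adjusted p = 0.0451, lost in 11 of 12 leave-outs) with knockdown and scramble. It was at 0.09 with knockdown and mimic (adjusted p = 0.889), and CD68 was at -0.02 with the mimic in wildtype cells (adjusted p = 0.973). PECAM1, an adhesion gene of endothelium, fell with the mimic in wildtype cells by 1.81 (SE 0.38, adjusted p = 0.00881), with 141.9, 52.4 and 57.8 normalised counts in scramble replicates 1 to 3. Of 5 replication histones 0 were called by edgeR with the mimic in wildtype cells (median -0.94, camera adjusted p = 0.254), and H1-2 alone rose with knockdown and mimic (1.08, SE 0.39, adjusted p = 0.0442, lost in 7 of 12 leave-outs).

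TCEAL9 (chromosome X, 103356489 to 103358462) was the only gene with a count of 0 in all 6 shRab27A libraries and at least 10 in all wildtype libraries, and 0 genes showed the reverse. Its 16 tested neighbours within 1 Mb had a median log2 change of -0.017 with scramble and -0.317 with the mimic, and the lowest were -0.69 and -0.77. Loss or silencing of the whole neighbourhood does not account for this (-0.017).

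Of 1952 genes called with knockdown and mimic at a log2 of at least 1, wildtype scramble replicate 1 deviated the same way in 1715 (87.9%), by a median share of 0.530 of the effect, under 0.25 in 500 and at least 0.5 in 1034. Replicate 2 minus replicate 3 correlated with that effect at 0.037 across genes.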
